A study of Mus musculus with 12 samples.

How the data were processed

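Neocortex of mouse embryos at embryonic day 13.5 was divided along its length, and RNA from its rostral end was compared with RNA from its caudal end on arrays that read 2 dyes at once, Cy3 and Cy5. Per the labels, each pool held tissue of 3 embryos, while the series' design text gives a lower minimum and says that the tissue came from single litters. There were 3 pools of the outbred strain MF1 and 3 of the inbred strain C57. Each pool was hybridised on 2 arrays with the dyes exchanged, which gave 12 arrays of 6 pools. Per the labels' protocols, total RNA was extracted with Trizol, and per the series' design text cDNA was amplified with the SMART method, a polymerase chain reaction from small amounts of RNA. The pool was the replicate in the fits of pool means. An alternative fit of the 12 arrays counted the 2 arrays of a pool as nearly independent. Nothing in the labels says that the pools of a strain came from separate litters. The p-values on pool means therefore measure the spread between these pools, part of which may be technical.

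The deposited values of each array were log2 ratios between its dyes, as read from the values themselves: they were signed, lay around 0, and had a ceiling of 16.61, the log2 of a ratio of 100000. Image analysis, background correction, any within-array normalization and the channel used as numerator are not given in the sources used here. The table held 21998 probes and 12 array columns, with 0 columns of other samples. Between 4.55% and 18.2% of probes had no value on an array. The 701 values at the ceiling were treated as missing. Array medians ran from -0.41 to 0.475, so each array was centred on its median, an alternative planned before the data were examined for the case that medians were not near 0. No spot intensities were used here, so an intensity-dependent dye correction could not be made, and signal over background is unknown; the number of arrays limits the precision.

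Of the probes, 16864 carried 1 gene symbol in the platform annotation, 139 carried several and 4995 had no entry; probes with several symbols were left unnamed. The Entrez identifier of 16184 probes was found in the RefSeq gene table, and 0 symbols were replaced. No coordinates are given, because the probes' genome build is not given in the sources used here. Probes of the same gene were averaged, which concerned 1069 genes.

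The direction of the ratios was inferred. Per the labels, rostral RNA was in Cy3 on 1 array of each pool and in Cy5 on the other. If the deposited values ran by dye, the deviations of both arrays of a pool from the mean of their strain and orientation had to correlate below 0. They did so with Spearman correlations across probes of -0.25, -0.22 and -0.35 in the MF1 pools and of -0.15 and -0.16 in C57 pools 1 and 2, while C57 pool 3 gave 0.00. The arrays with rostral RNA in Cy3 were therefore turned, with Cy5 over Cy3 as the assumed convention. The direction rostral over caudal is likely rather than known. Its basis is that the median of the caudal reference genes (-0.38) lay below that of the rostral reference genes (0.19), so these lists are not independent evidence of direction.

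A pool entered with both orientations present, and a feature needed at least 2 such pools per strain; 14418 features remained, of which 11490 were named genes. Pool means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per strain, 1 shared spread), with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were rostral against caudal cortex over both strains with equal weight, the same in MF1 and in C57, and the difference between the strains. Without a paper, the named genes followed a rule fixed before the data were examined: for both strains the 12 genes per side that passed with the same sign in every pool, filled up with the genes of smallest p and said not to pass; for each strain and for the strain difference the 5 genes of smallest p per side; every measured member of the caudal and rostral reference lists; and from each other list the members past the threshold, or the 2 of smallest p. Genes that passed under an alternative are named outside that rule, after their values were seen.

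The 24 gene lists were fixed before the data were examined. Besides the reference lists they covered FGF signalling, cortical hem and Wnt signalling, BMP and TGF-beta signalling, the retinoic acid pathway, the Notch pathway, area and axon guidance molecules, radial glia, cell cycle, intermediate progenitors, postmitotic neurons, Cajal-Retzius cells, ventral telencephalon, choroid plexus, diencephalon, red blood cells, blood vessels, meninges and mesenchyme, microglia and macrophages, hypoxia and glycolysis, immediate early and stress genes, ribosomal proteins and oxidative phosphorylation. They were tested against all other features with limma's cameraPR at a preset correlation of 0.01, since camera needs complete values, and with camera at an estimated correlation on features complete in all 6 pools. On the same features fry tested each list against no change, not against other features. An exact two-sided sign-flip test over the 6 pools was run on list medians, also against no change. Its smallest p is 0.03125, so that after adjustment over 24 lists a few lists alone could not pass. It gave that p for the cell cycle and both reference lists (adjusted p = 0.25) and does not bear on the calls of cameraPR.

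The fits were tested on simulated data with 14418 features. For both strains, pool means brought past adjusted p 0.05 0% of genes shifted by 0.5 log2 units, 47.8% of those shifted by 1 and 95.5% of those shifted by 2, against 0.06% of unshifted features. For the strain difference the shares were 0%, 0% and 0%. With the 12 arrays fitted singly, the shares for both strains were 23.9%, 76.1% and 95.5%, against 0.104% of unshifted features. Those for the strain difference were 0%, 6% and 63.6%. The simulated noise was drawn independently for every array, with no variation shared by the arrays of a pool. The simulation therefore cannot show whether the 12-array fit calls too many features where such shared variation exists.

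Alternatives planned before the data were examined were a fit of the 12 arrays with the pool as a random block (duplicateCorrelation, statmod 1.5.0) and a dye term, arrays scaled to the same spread, probes complete on the 12 arrays, pools counted with 1 orientation, each probe alone, a robust variance prior, array weights, stricter thresholds, either dye orientation alone, each strain fitted alone, the replicate number as a block, and each pool left out in turn. Arrays not centred, ceiling values kept and the lists in the 12-array fit were added after the data had been seen. Another log base was planned for the case that the base stayed open and was not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation and plots.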

Results

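Gene expression was compared between the rostral and the caudal neocortex of mouse embryos at E13.5, when cortical progenitors are dividing and neurons are being made. The question was which transcripts are graded along this axis, along which the later areas of the cortex are laid out. The strains were chosen to tell strain-dependent patterns from general ones. Each of 6 pools, 3 of the outbred strain MF1 and 3 of the inbred strain C57, gave rostral and caudal RNA that competed on the same arrays, so every value is a log2 ratio of rostral over caudal cortex. Between 17998 and 20997 of 21998 probes had a value on each of the 12 arrays. The share of probes without a value was 7.73% ± 2.72 (SD, n = 6 arrays) in MF1 and 14.6% ± 2.24 (SD, n = 6 arrays) in C57. The SD estimated from the median absolute deviation of the log2 ratios averaged 0.49 on the MF1 arrays and 0.74 on the C57 arrays. Each array held 1 strain, so differences between strains cannot be told apart from these differences between the sets of arrays. The sign of every ratio is the likely one, because the channel used as numerator was inferred.

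Among genes known to be graded along this axis, Nr2f1, a nuclear receptor that promotes caudal area identity, was lower rostrally in 6 of 6 pools, with a mean log2 ratio of -1.14 ± 0.57 (SD, n = 6), a 2.2-fold difference. Lhx2, a homeobox factor of cortical progenitors, had a ratio of -0.50 ± 0.13, and Fgfr3, an FGF receptor with a caudal bias, of -0.38 ± 0.37, both below 0 in 6 of 6 pools. On the rostral side Etv5, a transcription factor induced by FGF signals, had a ratio of 0.54 ± 0.05. Spry2, a feedback inhibitor of FGF signalling, had a ratio of 0.50 ± 0.19 and Pax6, a regulator of cortical progenitors, of 0.40 ± 0.18. All of these were above 0 in 6 of 6 pools. None of these 6 genes passed over all genes tested (limma, adjusted p between 0.147 for Nr2f1 and 0.484 for Fgfr3). Each passed adjusted over the list alone, with limma's adjusted p of 0.000187 for Nr2f1, 0.00509 for Lhx2, 0.0334 for Fgfr3, 0.00949 for Etv5, 0.0183 for Spry2 and 0.0325 for Pax6. Both probes of Nr2f1 were below 0, at -1.38 and -0.90. Those of Etv5 averaged 0.61 and 0.47 but disagreed within MF1, at 1.096, 0.65 and -0.0375 in pools 1 to 3 against 0.078, 0.28 and 1.001, so its small SD holds for their mean alone.

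Counted by list, 0 of the 5 measured caudal reference genes passed over all genes tested and 3 were lower adjusted over the list alone. Of the 9 measured rostral reference genes 0 passed over all genes tested and 3 were higher adjusted over the list alone. As sets, the caudal list had a median of -0.38 (limma's cameraPR, adjusted p = 0.00589) and the rostral list a median of 0.19 (adjusted p = 0.0481), with medians on the same side in 6 of 6 pools for each. With an estimated correlation neither call held, at adjusted p = 0.498 for each, and with fry the adjusted p was 0.067 and 0.0917. The caudal call was lost without C57 pool 1 (adjusted p = 0.0728). The rostral call was lost without MF1 pool 1 (0.165), MF1 pool 3 (0.084), C57 pool 1 (0.0728) or C57 pool 3 (0.342) and with arrays not centred (0.0734). Since the direction of the ratios rests on these lists, they carry no independent evidence of it. Emx2, a homeobox gene known for a caudal gradient, had a ratio of 0.09 ± 0.27, and Crym, a thyroid hormone binding protein, of -0.05 ± 0.31, each with 3 of 6 pools on either side. Among the rostral genes the secreted factors Fgf8 (0.19 ± 0.25), Fgf17 (-0.05 ± 0.41) and Fgf15 (-0.39 ± 0.61) did not pass adjusted over the list alone. Neither did the FGF targets Etv4 (0.08 ± 0.31), Dusp6 (0.26 ± 0.24, n = 5) and Spry4 (-0.16 ± 0.98, n = 5). The ratio of Emx2 was -0.10 and that of Etv4 -0.11 with arrays not centred. Dusp6 gave -0.07 and Spry4 0.22 in the fit of the 12 arrays, and Fgf17 gave 0.0022 with arrays scaled.

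**Figure D1:**
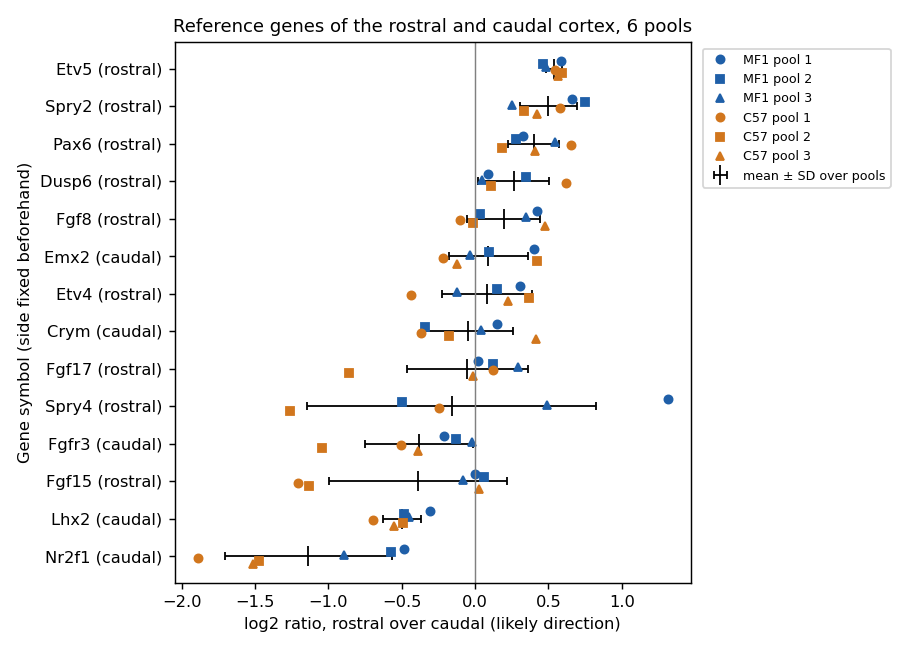
Log2 ratio of rostral over caudal cortex (horizontal axis, likely direction) of each measured reference gene (vertical axis, with the side fixed beforehand), with 1 point per pool and strain by colour; the black bar gives mean ± SD over pools. Etv5, Spry2 and Pax6 lie above 0 and Nr2f1, Lhx2 and Fgfr3 below 0 in 6 of 6 pools.

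Outside the reference genes, several of the genes of smallest p had the same sign in every pool measured. Higher rostrally in 6 of 6 pools were Fgfbp3, a secreted protein that binds FGFs, at 1.06 ± 0.11 (SD, n = 6, 2.09-fold), and Sfrp1, a secreted inhibitor of Wnt signalling, at 1.04 ± 0.19. So were Scrn1, a cytosolic protein of the secernin family, at 1.21 ± 0.38 and Pantr1, a long noncoding RNA transcribed beside Pou3f3, at 0.81 ± 0.10. Dct, an enzyme of melanin synthesis, had a ratio of 1.004 ± 0.32 and Mpped2, a metallophosphoesterase, of 1.02 ± 0.44. Pgm1, which interconverts glucose phosphates, had a ratio of 0.96 ± 0.58 and Rlbp1, a carrier of retinaldehyde, of 0.79 ± 0.20. Each of these 4 was above 0 in 6 of 6 pools. Lower rostrally in 6 of 6 pools were Rbm20, a splicing regulator, at -1.03 ± 0.24, Ltbp1, which binds latent TGF-beta in the matrix, at -1.17 ± 0.47, and Tenm2, an adhesion receptor of neurons, at -0.78 ± 0.15. The unannotated transcript 5730409K12Rik was at -1.47 ± 0.40 in 5 of 5 pools. The probes of Rbm20, at -0.51 and -1.54, disagreed within C57, at -0.18, 0.12 and -1.57 in pools 1 to 3 against -1.70, -1.59 and -0.12, so its sign in 6 of 6 pools and its SD hold for their mean alone. Those of Tenm2 differed in size, at -0.46, -0.98 and -0.89. Those of Sfrp1 gave 1.13 and 0.96.

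With limma on pool means 0 of 14418 features passed the adjusted threshold for both strains together, and the smallest adjusted p was 0.147, shared by Fgfbp3, Scrn1, Sfrp1, Rbm20 and Nr2f1. At an unadjusted p under 0.05 there were 1295 features, 8.98% of those tested, 626 higher rostrally and 669 lower; without MF1 pool 1 there were 798. With arrays not centred the median of all features was -0.18 and 6.64% of such features were higher rostrally in place of 48.3%, so ratios here are relative to the median of each array. Limma on the 12 arrays with the pool as a random block passed 25 features, 15 higher and 10 lower rostrally, and limma on features complete on the 12 arrays passed 6. The first of these fits counts the 2 arrays of a pool as nearly independent, with a consensus correlation of 0.00624. Its 1 dye term served both strains, so a dye effect that differs between strains can lower this correlation. The other settings run on pool means or a single dye orientation passed 0. Of the 25, 23 had a gene symbol: Nr2f1, Lhx2, Etv5, Fgfbp3, Sfrp1, Scrn1, Pantr1, Dct, Mpped2, Pgm1, Rlbp1, Rbm20, Ltbp1, Tenm2, 5730409K12Rik, Notch2, Gas1, Ptn, Tagln2, Tnfaip2, Mt1, Tmem41a and Tmem132cos. The 6 were Nr2f1, Sfrp1, Rbm20, Fgfbp3, Scrn1 and Gabra2, a subunit of a GABA receptor, at -1.23 and adjusted p = 0.0388 in that limma fit, against -0.60 ± 0.40 with the probes of the gene that were not complete included.

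**Figure D2:**
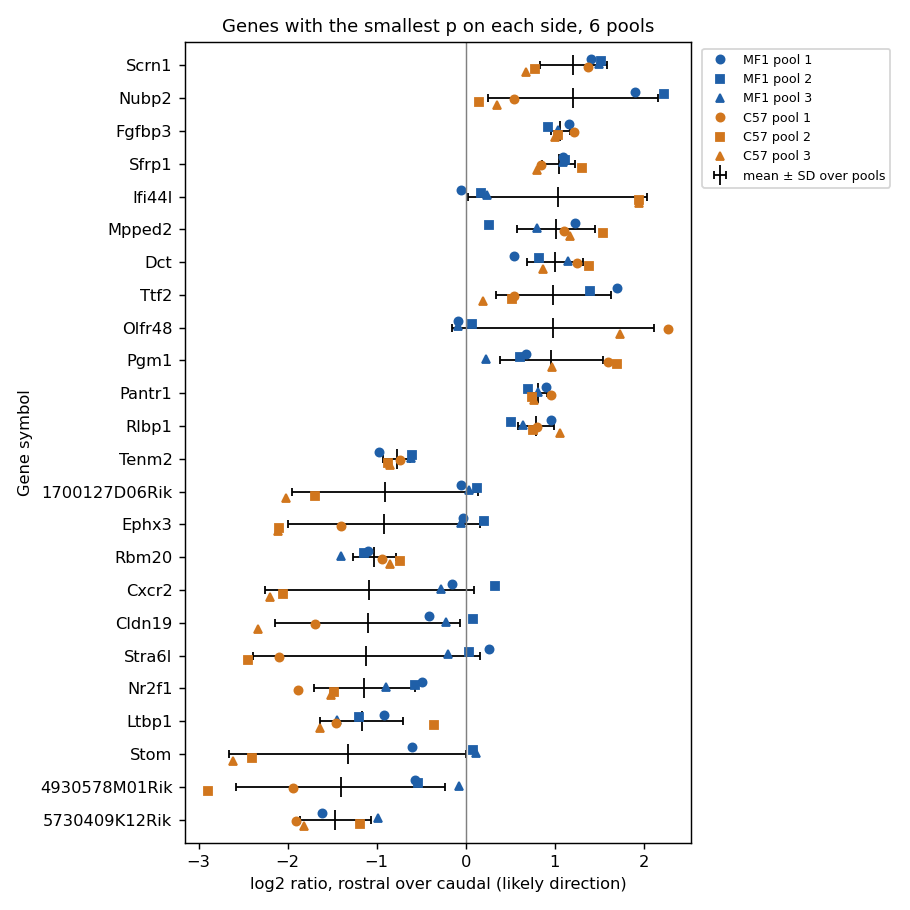
Log2 ratio of rostral over caudal cortex (horizontal axis, likely direction) of the genes of smallest p on each side (vertical axis), with 1 point per pool and strain by colour; the black bar gives mean ± SD over pools. Fgfbp3, Sfrp1 and Pantr1 have every pool above 0 with little spread. Stom, Stra6l and Cxcr2 lie far below 0 in C57 and closer to 0 in MF1, with Stom at -0.605 in MF1 pool 1. On pool means 0 genes passed the adjusted threshold.

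The remaining genes of smallest p had mean ratios of unlike size in the strains, but none of these differences passed (limma, adjusted p between 0.532 and 0.694). Nubp2, which takes part in the assembly of iron-sulphur proteins, and Ttf2, a transcription termination factor, were led by MF1, at 2.07 ± 0.23 and 1.55 ± 0.22 against 0.35 ± 0.20 and 0.42 ± 0.20 in C57 (SD, n = 2 or 3 pools per strain). The interferon-induced Ifi44l, the olfactory receptor Olfr48, the membrane protein Stom, Stra6l, the epoxide hydrolase Ephx3, the chemokine receptor Cxcr2, the claudin Cldn19 and the transcripts 4930578M01Rik and 1700127D06Rik had C57 means of 1.85 or more in size, and MF1 means of 0.39 or less in size. Ifi44l turned to -0.11 on the arrays with rostral RNA in Cy5 alone, as Cxcr2 did to 0.15, and Olfr48 turned to -0.51 on those with rostral RNA in Cy3 alone.

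By cameraPR, dividing-cell genes lay higher rostrally as a set. The cell cycle list of 53 measured genes had a median of 0.18 (cameraPR, adjusted p = 0.000169; adjusted p = 0.498 with an estimated correlation and 0.166 with fry) and a median above 0 in 6 of 6 pools. Of its members 41 were above 0 and 12 below. Rrm2, a subunit of ribonucleotide reductase, had a ratio of 0.51 ± 0.28 (SD, n = 6) and Pttg1, securin, of 0.40 ± 0.12. In this list 0 members passed over all genes tested or adjusted over the list alone. The list's median was -0.01 with arrays not centred, where all features had a median of -0.18. The cell cycle medians of the pools ran from 0.03 in MF1 pool 2 to 0.29 in MF1 pool 3.

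Genes of meninges and mesenchyme, the connective tissue that covers the cortex, lay lower rostrally over both strains. Their median was -0.11 over 32 genes (cameraPR, adjusted p = 0.0239, and 0.498 with an estimated correlation), below 0 in 5 of 6 pools. The list passed in C57 alone (cameraPR, median -0.17, adjusted p = 0.0112). In MF1 alone it did not pass (median -0.03, adjusted p = 0.701), with 14 members above 0 and 18 below. The strain difference did not pass either (cameraPR, adjusted p = 0.2485). Twist2, a mesenchymal transcription factor, had a ratio of -0.45 ± 0.49 (SD, n = 6), with -0.82 in C57 and -0.07 in MF1. Vtn, vitronectin, had a ratio of -0.44 ± 0.70, with -0.996 in C57 and 0.11 in MF1. In this list 0 members passed over all genes tested or adjusted over the list alone. The 81 oxidative phosphorylation genes had a median of 0.08 (adjusted p = 0.0239; adjusted p = 0.803 with an estimated correlation) with 3 of 6 pools on either side. Their median was -0.11 with arrays not centred and -0.0024 without MF1 pool 3. The call was lost in both cases (adjusted p of 0.38 and 0.788), without C57 pool 1 (0.304) and without C57 pool 3 (0.108). Atp5pb and Atp5b, subunits of ATP synthase, had ratios of 0.34 ± 0.25 and 0.35 ± 0.28. Ribosomal protein genes had a median of 0.08 over 64 genes (adjusted p = 0.0553), and their pool medians ran from -0.23 to 0.40. They passed without MF1 pool 1 (adjusted p = 0.0079), MF1 pool 2 (0.000795) or C57 pool 2 (0.00812), with ceiling values kept (0.0472) and in the 12-array fit (0.0313). With an estimated correlation their adjusted p was 0.803. Of the oxidative phosphorylation and ribosomal lists, 0 members passed over all genes tested or adjusted over the list alone. Without C57 pool 1 the only list of the 24 that passed was cell cycle; the meninges list gave adjusted p = 0.244 without that pool and 0.328 without MF1 pool 3.

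**Figure D3:**
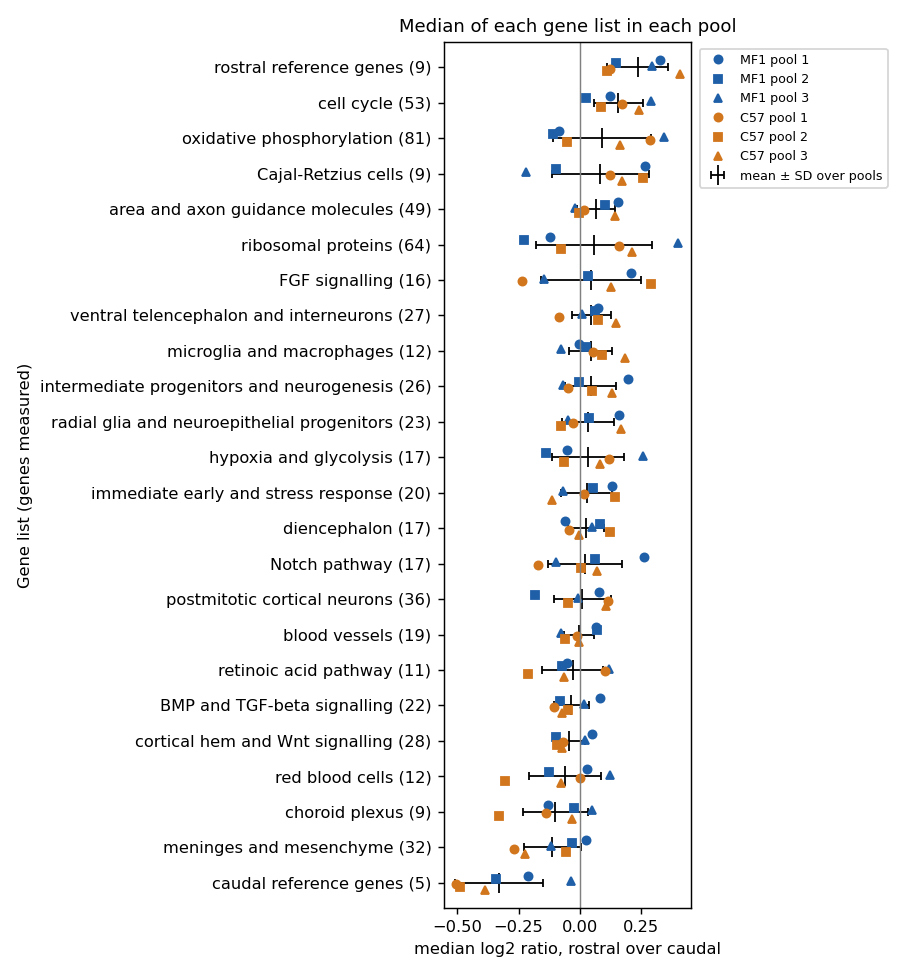
Median log2 ratio of rostral over caudal cortex (horizontal axis, likely direction) of the genes of each of the 24 lists (vertical axis), with 1 point per pool and strain by colour; the black bar gives mean ± SD over pools of these medians. The cell cycle and rostral reference medians lie above 0 and the caudal reference medians below 0 in 6 of 6 pools, and the ribosomal medians spread from -0.23 to 0.40.

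Signalling lists did not shift as sets, and single members stood out. Sfrp1 was the member of the cortical hem and Wnt list that passed adjusted over the list alone (adjusted p = 0.00143), and Lmx1a, a marker of the cortical hem, had a ratio of -1.33 ± 1.06 (SD, n = 4). Ltbp1 passed adjusted over the BMP and TGF-beta list alone (adjusted p = 0.0123). In that list Msx2, a BMP target, had a ratio of 0.40 ± 0.39, with 0.74 in C57 and 0.06 in MF1. Notch2, a Notch receptor, passed adjusted over the Notch list alone (adjusted p = 0.0123) at -0.85 ± 0.71, with -1.43 in C57 and -0.26 in MF1. Hes5, a Notch target, had a ratio of 0.49 ± 0.50, with 0.89 in C57 and 0.09 in MF1. In the FGF list, with 0 members past adjustment over the list alone, Fgf11 was at -0.62 ± 0.45 and Flrt3, an FGF receptor partner, at -0.62 ± 0.50. In the retinoic acid list, also with 0, the retinal reductase Dhrs3 was at -0.53 ± 0.57 and the binding protein Crabp1 at -0.38 ± 0.63. Their means were -0.99 and -0.70 in C57 and -0.07 for each in MF1. Of 49 area and guidance molecules 0 passed adjusted over the list alone, with the netrin receptor Dcc at 0.62 ± 0.36 and the cadherin Cdh10 at 0.62 ± 0.41. The probes of Cdh10 disagreed (1.08, 0.89 and -0.35). Those of Dcc averaged 0.56 and 0.67, but the second ran from -0.145 to 0.35 in MF1 and reached 1.88 in C57 pool 1. Those of Fgf11 were at -0.40 and -1.12, the second with no value in MF1 pools 1 and 3. For these 6 lists 0 members passed over all genes tested, and the adjusted p of the sets was 0.499 or more (limma's cameraPR).

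Cell type lists of the cortex itself had medians between 0.00 for postmitotic neurons and 0.16 for Cajal-Retzius cells, and 0 of them passed (cameraPR, adjusted p of 0.499 or more). Among radial glia genes the adhesion molecule Cdh2 had a ratio of 0.49 ± 0.24 (SD, n = 6). Among genes of intermediate progenitors Pou3f2, a transcription factor, had a ratio of 0.43 ± 0.21 and Rnd2, a GTPase of migrating neurons, of 0.35 ± 0.15. Among those of postmitotic neurons the transcription factors Foxp1 and Bcl11b had ratios of 0.40 ± 0.15 and 0.41 ± 0.24. These 5 genes were above 0 in 6 of 6 pools. The probes of Pou3f2 disagreed, at -0.04 and 0.89, and those of Bcl11b differed in size, at 0.68 and 0.14, each with 1 pool below 0. For Cajal-Retzius cells, Ebf1 was at 0.60 ± 1.42 (n = 4), with MF1 and C57 on opposite sides, and Cxcr4 at -0.58 ± 0.59. In the list of the ventral telencephalon, which holds the sources of interneurons, Zic1 was higher at 0.78 ± 0.31 and Dlx5 lower at -0.63 ± 0.32 rostrally, both adjusted over the list alone (adjusted p of 0.0324 and 0.0334). For these lists 0 members passed over all genes tested, and in the first 4 of them 0 passed adjusted over the list alone.

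Markers of neighbouring tissues and of other cells did not shift as sets outside the meninges list, with 0 members past adjustment over all genes or over the list alone. Choroid plexus genes had a median of -0.08 (cameraPR, adjusted p = 0.447), with Ttr, the transport protein made by choroid plexus, at -0.92 ± 1.09 (SD, n = 6) and the water channel Aqp1 at -0.61 ± 0.70. Diencephalic genes had a median of -0.08 (Irx1 0.29 ± 0.13, Foxa2 -0.41 ± 0.44), red blood cell genes of -0.06 (Gata1 0.41 ± 0.19, n = 5, Hebp1 -0.34 ± 0.66) and blood vessel genes of -0.01 (Icam2 -0.79 ± 1.20, Acta2 -0.38 ± 0.65). Microglial genes had a median of -0.01 and a mean of -0.02, though cameraPR ranked them on the upper side, with Fcer1g at 0.34 ± 0.48 (n = 5) and Tyrobp at 0.26 ± 0.21. Genes of hypoxia and glycolysis had a median of 0.03 (Ndrg1 -0.43 ± 0.33, Tpi1 0.19 ± 0.17) and immediate early and stress genes of 0.01 (Gadd45b 0.70 ± 0.23, n = 5, Btg1 -0.46 ± 0.30). Among ribosomal genes Rps4l was at -0.56 ± 0.48 and Rpl3 at 0.22 ± 0.17.

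In MF1 alone, the highest rostral ratios among the genes of smallest p were those of 4930417O22Rik at 2.46 ± 0.54 (SD, n = 2 or 3 pools for each gene), Nubp2 at 2.07 ± 0.23, Scrn1 at 1.48 ± 0.06, 4930503H13Rik at 1.13 ± 0.09 and Fgfbp3 at 1.04 ± 0.12. The lowest were those of B230112J18Rik at -1.64 ± 0.17, Ppp1cc, a catalytic subunit of protein phosphatase 1, at -1.41 ± 0.27, Ccdc112 at -1.41 ± 0.04, 4930528A17Rik at -1.41 ± 0.16 and Rbm20 at -1.21 ± 0.16. With rostral RNA in Cy3 alone Nubp2 was at 0.68 and Ccdc112 at -0.79. With rostral RNA in Cy5 alone 4930417O22Rik was at 1.04, Rbm20 at -0.62, B230112J18Rik at -0.88 and 4930528A17Rik at -0.88. As sets, the rostral reference genes had a median of 0.27 (cameraPR, adjusted p = 0.00203; adjusted p = 0.627 with an estimated correlation). The cell cycle genes had a median of 0.15 (adjusted p = 0.00203; adjusted p = 0.902 with an estimated correlation). The caudal reference genes had a median of -0.12 with adjusted p = 0.0991. With limma 0 features passed, 628 had an unadjusted p under 0.05 (951 without MF1 pool 3, 1376 with array weights, 1048 with arrays scaled) and the smallest adjusted p was 0.364. Limma on the 12 arrays passed 3, Sfrp1, Fgfbp3 and Scrn1, all higher rostrally. MF1 pool 3 ran against pools 1 and 2 across genes, with Spearman correlations of -0.22 and -0.21, while pools 1 and 2 correlated at 0.28. Genes are not independent replicates.

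In C57 alone, Pde9a, a phosphodiesterase of cyclic GMP, had a ratio of 2.36 ± 0.76 (SD, n = 2 or 3 pools for each gene), Olfr48 of 2.004 ± 0.38, Ifi44l of 1.95 (2 pools), Pgm1 of 1.42 ± 0.40 and Fgfbp3 of 1.09 ± 0.11. On the caudal side Nr2f1 had a ratio of -1.63 ± 0.23, Stom of -2.51 ± 0.15, Stra6l of -2.27 ± 0.24, Ephx3 of -1.87 ± 0.41 and 1700127D06Rik of -1.85 ± 0.23. On arrays with rostral RNA in Cy3 alone Olfr48 turned to -0.98, and Stom was at -4.48, 1700127D06Rik at -2.84, Ifi44l at 3.81, Pde9a at 1.055 and Fgfbp3 at 0.72. On those with rostral RNA in Cy5 alone Ifi44l turned to -0.81, and Stom was at -0.67, 1700127D06Rik at -0.32, Stra6l at -1.37 and Olfr48 at 3.64. As sets, caudal reference genes (median -0.58, cameraPR, adjusted p = 0.0061) and meninges genes (-0.17, adjusted p = 0.0112) lay lower. Cell cycle (cameraPR, 0.17, adjusted p = 0.0061), oxidative phosphorylation (0.11, adjusted p = 0.0116) and ribosomal genes (0.10, adjusted p = 0.0494) lay higher rostrally. With an estimated correlation none of these 5 calls held (adjusted p between 0.675 and 0.871). With limma 0 features passed, 1400 had an unadjusted p under 0.05 (901 without C57 pool 3) and the smallest adjusted p was 0.177. With arrays scaled 872 features had such a p, fewer than the 1048 of MF1 in that setting. Limma on the 12 arrays passed 11: Nr2f1, Tenm2, Notch2 and 5730409K12Rik lower, Sfrp1, Fgfbp3, Mpped2, Pgm1 and Pantr1 higher, and 2 unnamed probes lower. On arrays of a single orientation 188 features (rostral RNA in Cy3) and 118 (rostral RNA in Cy5) passed. There 56.2% and 41.7% of features at an unadjusted p under 0.05 were higher rostrally, against 43.6% on pool means. Limma called a dye effect in 1371 features in C57, 253 over both strains and 0 in MF1, where 1190 had an unadjusted p under 0.05.

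Between the strains, the ratio of Nr2f1 was less negative in MF1 by 0.97 ± 0.24 (SE) and that of Notch2 by 1.18 ± 0.29, and neither difference passed (limma, adjusted p of 0.693 and 0.694). The difference of Nr2f1 holds for the mean of its probes. One probe ran from -0.65 to -1.49 in MF1 and from -1.49 to -2.03 in C57. The other ran from -0.08 to -0.32 in MF1 and from -1.43 to -1.75 in C57. The genes of smallest p with the ratio higher in MF1 were 4930417O22Rik (3.56 ± 0.33, SE), Prr32 (2.59 ± 0.33), Stra6l (2.30 ± 0.28), Ephx3 (1.91 ± 0.27) and 1700127D06Rik (1.89 ± 0.26). Those with the ratio higher in C57 were Obp1a (-4.26 ± 0.57), an odorant-binding protein, Pde9a (-2.36 ± 0.38), Olfr48 (-2.04 ± 0.28), Ppp1cc (-1.93 ± 0.30) and Ifi44l (-1.83 ± 0.25). With rostral RNA in Cy3 alone the difference turned for Olfr48 (0.94), shrank for Prr32 (0.61) and Pde9a (-1.22) and grew for Ifi44l (-4.17). With rostral RNA in Cy5 alone it turned for Ifi44l (1.41), shrank for 1700127D06Rik (0.41), Stra6l (1.38) and 4930417O22Rik (2.33) and grew for Olfr48 (-3.67) and Prr32 (4.14). Fgfbp3, Pantr1, Etv5, Ltbp1 and Tenm2 differed by -0.05 ± 0.21, -0.02 ± 0.21, -0.06 ± 0.20, -0.04 ± 0.38 and 0.09 ± 0.22. A p that misses the threshold does not show that they are alike. With limma 0 features passed, 879 had an unadjusted p under 0.05 (526 without MF1 pool 2), the smallest adjusted p was 0.532, and limma on the 12 arrays passed 0 too. Of the lists 0 passed (cameraPR), and the caudal reference and meninges lists had the smallest adjusted p, 0.248 for each. Both passed in the 12-array fit (cameraPR, adjusted p = 0.0462 for each), and the meninges list passed without C57 pool 2 (0.0174).

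Across all 14418 features the mean ratios of the strains correlated with Pearson's r of 0.10 and Spearman's rho of 0.14, and 56.5% had the same sign. Pearson's r was 0.060 without MF1 pool 1, and Spearman's rho was 0.087 without MF1 pool 3 and 0.216 without MF1 pool 2. Among the 413 features at an unadjusted p under 0.01 in C57, 63.2% had the same sign in MF1. The same sign in all 6 pools was found in 633 of 10596 features with 6 pools, 5.97% against 3.125% by chance with independent features. Features are not independent, and 3 of the other ways of turning the signs of whole pools gave more, up to 887.

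**Figure D4:**
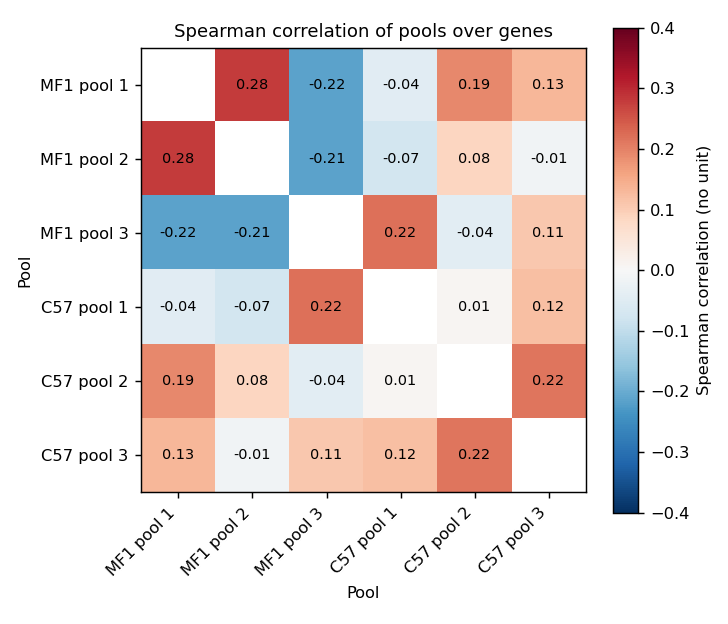
Spearman correlation across genes of the log2 ratios of each pair of pools (both axes list the 6 pools; colour gives the correlation, which has no unit). MF1 pools 1 and 2 correlate at 0.28, MF1 pool 3 correlates with them at -0.22 and -0.21 and with C57 pool 1 at 0.22, and pairs within C57 range from 0.01 to 0.22.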

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

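The tests on MF1 pool 3 were chosen after its result was seen, among them the reference genes and the 20 strongest genes as tests for crossed labels and the test of single arrays, while those on C57 pool 1 were set before. A sample was singled out where its gap to the nearest other sample took an unusually large part of the range of the group, which chance alone does in about 1 in 20 groups. Of 119 groups examined (87 genes, 24 lists and 8 measures of the arrays), 5 had such a sample, each of them a gene. That is no more than this rate would give by chance. Fgf17 stood at -0.86 in C57 pool 2 against -0.02 to 0.29 in the other pools. Dlx5 stood at -0.0175 in MF1 pool 2 against -0.95 to -0.64, Gata1 at 0.71 in C57 pool 3 against 0.25 to 0.36 in 4 others, and Icam2 at -3.12 in C57 pool 1 against -0.96 to 0.07. Ttr stood at 1.19 in C57 pool 1 against -1.72 to -0.84 in the other pools.

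Of these 5 genes Ttr, made in quantity by the choroid plexus, had its sign turned in that pool alone; so had the ribosomal Rps4l, at 0.22 against -1.14 to -0.32, with a smaller gap. Crossed rostral and caudal labels in that pool alone are argued against. Of 200 genes chosen on the other 5 pools, 64.5% had the same sign in C57 pool 1 (95% exact binomial interval 57.4% to 71.1%, across genes, which are not independent). The reference genes of that pool, at 0.30 ± 0.19 (SE) on their fixed side with 10 of 14 genes on it, did not decide by themselves. With that pool turned alone, 983 features in place of 1295 had an unadjusted limma p under 0.05 for both strains. With MF1 pool 3 turned as well there were 1729, so crossed labels in both pools are not excluded. Choroid plexus tissue on the rostral side may be the source, but the other choroid plexus genes had a median of -0.19 there, below 0. In the other pools their medians ran from -0.22 to 0.25, with the sign of Ttr in MF1 pools 1 and 2 and C57 pool 2 and the other sign in MF1 pool 3 and C57 pool 3, so this test leaves the explanation open. No biological explanation was tested.

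MF1 pool 3 ran against MF1 pools 1 and 2, and its ribosomal median was 0.40 against -0.12 and -0.23. For crossed labels, the test written first, the sign of 200 genes chosen on the other 5 pools, gave 50.5% (95% exact binomial interval 43.4% to 57.6%) and met neither bound set for it. The reference genes, which also served to fix the direction of all ratios, averaged 0.26 ± 0.08 (SE) on their fixed side with 11 of 14 genes on it, which speaks against crossed labels. The 20 genes of smallest p in the other 5 pools averaged 0.30 ± 0.18 (SE) toward their sign there, with 12 of 20 on it, which misses the bound of 2 SE above 0 set for both averages. Among them Scrn1 (1.495), Sfrp1 (1.098), Fgfbp3 (1.037), Nr2f1 (-0.89) and Rbm20 (-1.397) kept their sign and R3hcc1l (2.04, against -1.14) and Gja1 (0.45, against -1.12) did not. Crossed labels would turn all of them. With the signs of MF1 pool 3 turned, 1581 features in place of 1295 had an unadjusted limma p under 0.05 for both strains, and 1378 in place of 628 in MF1. The same turn left 597 features in place of 633 with the same sign in all 6 pools, and 0 lists in place of 5 past the threshold. These values go both ways, so crossed labels are not excluded. A bias of 1 of its 2 arrays as the whole cause is argued against, since each array ran against the mean of MF1 pools 1 and 2, with Spearman correlations across probes of -0.127 (rostral RNA in Cy3) and -0.112 (rostral RNA in Cy5) after the mean dye ratio of the C57 pools was taken off. A difference in RNA or amplified cDNA that moves ribosomal and respiratory transcripts as a block may account for the pattern, as its ribosomal median of 0.40 lay on the other side of 0, but this value was known when the test was set. A biological difference between litters stays open and was not tested.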

How the results depend on the processing

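The settings arrays not centred, ceiling values kept and the lists in the 12-array fit were chosen after the data were seen; the others were planned. The replicate numbers do not pair the pools of the strains: same-numbered pools correlated across genes at -0.14, 0.06 and 0.00 in their deviations, and with the replicate number as a block the strain difference had 0 features past the threshold (limma; 439 at an unadjusted p under 0.05), as without it. Counts of features past the adjusted threshold moved in few settings, while counts at an unadjusted p under 0.05 moved in more. The fit of the 12 arrays passed 25, 3 and 11 features for both strains, MF1 and C57, in place of 0. The 2 arrays of a pool had a consensus correlation of 0.00624 there, so that fit counts them as nearly independent. Its dye term was shared by the strains, while on pool means limma called a strain difference in the dye effect in 45 features. Such a difference enters the 2 turned arrays of a pool with opposite signs. The low correlation therefore does not show that these arrays share no variation of their pool. Complete probes passed 6 for both strains, with fewer features tested, and gave 101 dye effects in place of 253 and a correlation of the strains of 0.18 in place of 0.10, which was 0.060 without MF1 pool 1, 0.034 with 1 orientation enough, 0.030 and 0.055 with rostral RNA in Cy3 or Cy5 alone and 0.054 with ceiling values kept. At an unadjusted p under 0.05, both strains had 798 features in place of 1295 without MF1 pool 1, and MF1 951 in place of 628 without MF1 pool 3. C57 had 901 in place of 1400 without C57 pool 3, and the strain difference 526 in place of 879 without MF1 pool 2. Each of these fits tested fewer features. Both strains had 2168 with arrays not centred. With array weights MF1 had 1376 and the strain difference 1377. With arrays scaled MF1 had 1048 and C57 872. Fitted alone, MF1 had 562 and C57 1007. With rostral RNA in Cy3 or Cy5 alone both strains had 2554 and 2592, with more features tested. Single orientations, in which the dye bias is not removed, passed 188 (Cy3) and 118 (Cy5) features in C57. For both strains 5 lists became 0 with an estimated correlation, 0 with fry, 3 with arrays not centred, and 1 to 6 with a pool left out (1 without C57 pool 1, 2 without MF1 pool 3, 3 without C57 pool 3). For the strain difference 0 lists became 2 in the 12-array fit and 0 to 2 with a pool left out (2 without MF1 pool 3 and without C57 pool 2). The dye effect ranged from 0 to 348 features with a pool left out, at 0 without each MF1 pool. With the sign turned, the caudal reference median was 0.38, by construction.

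Of 108 gene values 21 changed sign in some alternative; for these the cause was not tested. With rostral RNA in Cy5 alone, Ifi44l went to -0.11 (-0.81 in C57, 1.41 for the strain difference), Cxcr2 to 0.15, Emx2 to -0.11, Crym to 0.45, Fgf17 to 0.26, Crabp1 to 0.22, Aqp1 to 0.20, Ndrg1 to 0.009 and Tpi1 to -0.78. With rostral RNA in Cy3 alone, Olfr48 went to -0.51 (-0.98 in C57, 0.94 for the strain difference), Dusp6 to -0.82, Spry4 to 1.72, Hebp1 to 0.082, Icam2 to 0.25, Fcer1g to -0.023 and Tyrobp to -0.074. With arrays not centred, Emx2 went to -0.10, Etv4 to -0.11 and Tpi1 to -0.0018. In the 12-array fit Dusp6 went to -0.074 and Spry4 to 0.22, with 1 orientation enough to -0.42 and 0.26, and with arrays scaled Fgf17 to 0.0022. With a pool left out, Emx2 ranged from -0.0074 to 0.15, Crym from -0.16 to 0.034, Spry4 from -0.38 to 0.074 and Fgf17 from -0.15 to 0.10. Cell cycle passed in each scaling alternative and with any pool left out (medians 0.13 to 0.23 there), but not with an estimated correlation (adjusted p = 0.498) or with fry (0.166). Another log base was not run, since the ceiling settled the base. Signal over background, which limits weak probes, is unknown.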

Other observations

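The split counts of single features and of features with the same sign in all pools, the correlations with ribosomal medians, the final form of the progenitor test and the choice of the genes in the next paragraph were made after results were seen, while the split counts of lists and the ribosomal covariate were set before.

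Genes that passed limma in the 12-array fit but were named by no rule included signalling molecules. Gas1, a membrane co-receptor of Hedgehog signals, was higher rostrally at 0.81 ± 0.30 (SD, n = 6; limma, 12-array adjusted p = 0.0274), and so were Ptn, the growth factor pleiotrophin, at 0.45 ± 0.10 (0.0459), Tagln2, an actin-binding protein, at 0.69 ± 0.17 (0.0214), Tnfaip2, a protein induced by tumour necrosis factor, at 0.60 ± 0.29 (0.0464) and Tmem41a at 0.75 ± 0.40 (0.0345). Mt1, a metal-binding metallothionein, was lower at -0.62 ± 0.15 (0.0214). Each had its sign in 6 of 6 pools, and 0 of these 6 passed limma on pool means, where the smallest adjusted p among them was 0.295, for Tagln2.

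Pool medians of the other 23 lists were compared with those of the ribosomal protein genes over the 6 pools, and 0 of the 23 relations passed the correction (exact permutation; 3 at an unadjusted p under 0.05 by Pearson's r, 3 by Spearman's rho). Pool medians of the cell cycle list correlated with ribosomal medians at Pearson's r = 0.968 (exact permutation p = 0.00417, adjusted over 23 relations 0.0639) and Spearman's rho = 0.943 (exact p = 0.0167, adjusted 0.192). Hypoxia and glycolysis gave r = 0.982 (exact p = 0.00556, adjusted 0.0639) and rho = 0.886 (exact p = 0.0333, adjusted 0.256), and oxidative phosphorylation r = 0.952 (exact p = 0.00833, adjusted 0.0639) and rho = 0.943 (exact p = 0.0167, adjusted 0.192). Without MF1 pools 2 and 3, the farthest from the ribosomal median, r was 0.901, 0.944 and 0.917. These relations were not tested within strains, where 3 pools per strain would make such a test weak.

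The cell cycle list lay higher rostrally in 6 of 6 pools, a call of cameraPR that was absent with an estimated correlation (adjusted p = 0.498) and with fry (0.166). With the ribosomal median of each pool as a covariate the cell cycle median was 0.17 (cameraPR, adjusted p = 4.87e-05) against 0.19 without it (adjusted p = 3.91e-06), on 48 genes measured in 6 pools. This met the bound set against the block of ribosomal transcripts as its whole cause. Ribosomal medians averaged only 0.058 over pools, so the covariate could move the cell cycle median little, and the test cannot decide. With the covariate the calls of the oxidative phosphorylation (adjusted p = 0.506), rostral reference (0.0671) and meninges lists (0.0671) were lost. The caudal reference list kept its call (0.0139). A larger share of progenitors on the rostral side may be involved and stays open. The cell cycle median lay above the radial glia median in 4 of 6 pools, by 0.12 ± 0.14 (SD; exact two-sided sign-flip p = 0.125), which the rule first written would have counted for this explanation; after the result was seen the radial glia list was also required to pass, and it did not (adjusted p = 0.741). A biological difference in developmental timing along the axis was not tested.

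Signs of whole pools were turned to see how often other arrangements gave as much. For both strains 5 of the 32 arrangements, the real one included, gave as many features at an unadjusted p under 0.05, so chance is not excluded: the real count was 1295 and the highest other 1729, with MF1 pool 3 and C57 pool 1 turned, which correlate with each other at 0.22. For features with the same sign in all 6 pools 4 of 32 gave as many (real 633, highest other 887, with the same pools turned), so chance is not excluded. For both kinds of feature count, every other arrangement that reached the real count had MF1 pool 3 turned. Variation shared between pools enters these counts, so they do not show what chance alone would give. For the lists 3 of 32 gave as many as the real 5, the highest other also being 5, so chance is not excluded there either. The remaining arrangements are too few for a share under 0.05. In MF1 2 of 4 gave as many (real 628, highest other 1378, with pool 3 turned), and in C57 1 of 4 (real 1400, highest other 1190). For the strain difference 2 of 10 splits gave as many (real 879, highest other 1303), and for its lists 10 of 10 (real 0, highest other 3).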
